A study of Homo sapiens with 9 samples.

How the data were processed

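RNA-seq counts of 9 libraries of the human astrocytoma line SW1783 were analysed. The cells were grown in L-15 medium with 10% fetal bovine serum and treated for 24 h. The groups were vehicle (DMSO, replicates 1 to 3) and 70% ethanol extracts of Poria Cocos and of Atractylodis Rhizoma at 20, 100 and 500 µg/mL, with 1 library each, all numbered replicate 2. The sample labels give the vehicle as 0.1% DMSO, whereas the series design gives 2%, and this was not settled. For the treated libraries the labels give no DMSO percentage. All 9 libraries carry the same batch letter, and the labels do not say whether the replicates were separate cultures. Per the submitters' processing notes, RNA with an integrity number above 7 was made into libraries with the MGIEasy RNA Directional kit and sequenced as paired reads of 100 bases. Reads were checked with FastQC 0.11.9, trimmed with Trim Galore 0.6.5, aligned to hg38 with STAR 2.7.3a and counted with RSEM 1.3.3. The annotation release was not given in the sources used here.

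The deposited values are RSEM expected counts per gene, and each expected count was rounded to a whole number. The table holds 60675 Ensembl genes in 279 columns, of which 9 belong to these samples, and 270 columns of other samples were not used here. Symbols and GRCh38 positions came from GENCODE 29 and a gene name table, which gave a symbol to 57055 genes, and the 3620 genes with none held between 0.031% and 0.033% of each library's counts. Library totals ran from 40269708 to 48905602 counts, and between 24614 and 25705 genes had counts. Mitochondrial transcripts made up between 5.384% and 6.971% of counts. At this depth, counting error is small for well expressed genes, where the number of libraries limits precision, but it counts for genes near the limit of detection such as CYP1A1.

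Tests used edgeR 4.0.16 in R 4.3.3, with TMM scaling, filterByExpr (count minimum 10, total minimum 15), quasi-likelihood fits with robust empirical Bayes, and Benjamini-Hochberg adjustment with a threshold of 0.05. This left 18356 genes tested and 42319 not tested. The dose trend was fitted on all 9 libraries with 1 slope per extract over the steps 0, 1, 2 and 3 for vehicle, 20, 100 and 500 µg/mL, which left 6 residual degrees of freedom, and the difference between the slopes was tested in the same fit. Single doses against vehicle, and the extracts against each other at each dose, came from a fit with 7 groups and 2 residual degrees of freedom, in which each lone library is assumed to vary like the vehicle libraries. Treated against vehicle compared all 6 treated libraries with the 3 vehicle libraries, with 7 residual degrees of freedom. The common biological coefficient of variation was 4.97% in the trend fit, 2.58% in the fit of single doses and 5.49% in the last. SE is the log2 change divided by the square root of F. Principal components used log2 CPM (prior count 2) of 11583 genes with a mean log2 CPM of at least 2.

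The slope within the treated libraries came from the trend fit with an added offset per extract, so that only the 3 treated doses set the slope (4 residual degrees of freedom). Part of these degrees of freedom come from the spread of the vehicle libraries. The correction for GC content and transcript length fitted natural splines (5 degrees of freedom) to each library's log2 deviation over genes with a mean log2 CPM of at least 1, and entered the fitted values as offsets. It used GC content and the longest annotated transcript of each gene.

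The 35 gene lists were written before the data were examined, as were the groups, the models, the thresholds, the rule for naming genes and the first set of alternatives. They cover cholesterol, liver X receptor, fatty acid synthesis and oxidation, aryl hydrocarbon receptor, NRF2, metallothioneins, integrated stress response, endoplasmic reticulum chaperones, heat shock, p53, DNA replication, mitosis, FOXO, NF-kB, interferon, hypoxia, immediate early, TGF-beta and YAP, matrix, metalloproteinases, autophagy, iron, ribosomal proteins, oxidative phosphorylation, mitochondrial mRNAs, histones, long nuclear RNAs, and markers of astrocytes, mesenchymal, neuronal, myeloid, epithelial, hepatocyte and endothelial cells. Lists with at least 4 tested members were tested with camera in limma 3.58.1 (preset correlation 0.01, adjusted over the lists of all comparisons in the same fit) and again with an estimated correlation. Each member was also adjusted over its list alone. The mitochondrial mRNA, histone and long nuclear RNA lists were fixed as signs of RNA quality.

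Genes were named by rule: the 10 largest positive and 10 largest negative slopes per extract among genes past the threshold with a mean log2 CPM of at least 2, the 5 largest each way for the difference, for treated against vehicle and for each extract at 500 µg/mL, up to 4 members per list with the smallest p, and 20 fixed genes. The text describes a part of them. List members that moved against their list were named after their values were seen. Some genes that the rule chose are not reported here.

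Alternatives were RLE scaling, DESeq2 1.42.0, limma-voom, a filter of CPM of at least 1 in 3 libraries, no filter, fits without robust estimation, leaving out each library, vehicle replicate 2 as the only control, dose itself, the treated doses only, the mean of the 3 doses, and only the libraries of 1 extract with vehicle. The GC and length correction, alone and with the treated doses only, and the treated doses only for gene lists were chosen after seeing the data. Dose steps were reassigned over the 6 libraries of each extract's fit in 60 assignments with the real one included, the 84 splits into 6 and 3 libraries were all run, and the extract labels were swapped within doses in 4 ways. Changes shared by the extracts were compared with 10 simulations of unchanged groups.

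The pipeline was tested on simulated data with 100 changed genes of each size among 18356. The trend fit found 61% of slopes of 0.1 and 99% of slopes of 0.3, with 6 false calls. The difference of slopes was found in 45% and 100% (8 false calls), and the slope within the treated libraries in 18% and 94% (3 false calls). A single dose against vehicle found 71% of log2 changes of 0.3 and 100% of changes of 1 (6 false calls), and treated against vehicle found 80% and 100% (5 false calls). Tables were read with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.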

Results

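SW1783 is a human astrocytoma line, and it was treated for 24 h with 70% ethanol extracts of Poria Cocos or Atractylodis Rhizoma at 20, 100 or 500 µg/mL. Poria is a fungus and Atractylodis Rhizoma is a plant rhizome, and both are used as tonifying herbal medicines. The 3 vehicle libraries (DMSO) were compared with 6 treated libraries, 1 for each extract and dose. No treated condition has a replicate, so its p-values rest on the spread of the vehicle libraries, or on the scatter around a dose trend. Those p-values measure only the spread between these samples, which may be technical, because the labels do not say that the libraries came from separate cultures. Slopes are log2 changes per 5-fold dose step, given ± SE from 9 libraries, and their p-values come from the edgeR quasi-likelihood test, adjusted over 18356 genes unless stated. Vehicle levels are mean CPM (counts scaled by the library total times its TMM factor) ± SD (n = 3).

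All treated libraries stood apart from vehicle. Counts of library pairs were also compared by chi-square per degree of freedom, which was 2.46 to 3.44 between vehicle libraries. Poria at 20 µg/mL and Atractylodis at 100 µg/mL were almost as alike (3.47), while each lay 15.69 to 20.12 from the vehicle libraries. Most of the shift of that pair from vehicle was thus shared by the extracts. Other pairs of treated libraries differed more, with 7.79 to 21.65. On the first principal component, with 49.4% of the variance, the vehicle libraries lay between -13.3 and -12.3, and the treated libraries between 2.56 and 9.93. The same direction ran along the GC content of the genes: the change between treated and vehicle libraries had a Spearman rho of -0.429 with GC content. Genes called higher in the treated libraries had a median GC content of 42.4%, against 55.8% for genes called lower. The slopes within the treated libraries had a rho of -0.102 with GC content for Poria and -0.407 for Atractylodis, and the difference between the trends of the extracts had -0.041. For part of the genes, trends are therefore given beside the slope within the treated libraries alone, which does not use the vehicle level, or beside a correction for GC content and transcript length that was chosen after seeing the data. The p-values of the slope within the treated libraries still rest in part on the spread of the vehicle libraries. Of the genes called for a trend from vehicle, 293 of 3815 for Poria and 523 of 3495 for Atractylodis were also called within the treated libraries. That fit found only 18% of simulated slopes of 0.1. The Atractylodis library at 20 µg/mL was the lowest on the second component (-10.83) and the third (-8.69). Its deviation from vehicle had a rho of -0.14 with GC content, against -0.487 to -0.384 in the other treated libraries. It is the lowest dose in every Atractylodis slope within the treated libraries, so those slopes lean on it. With the GC correction, 486 genes passed there in place of 742.

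**Figure D1:**
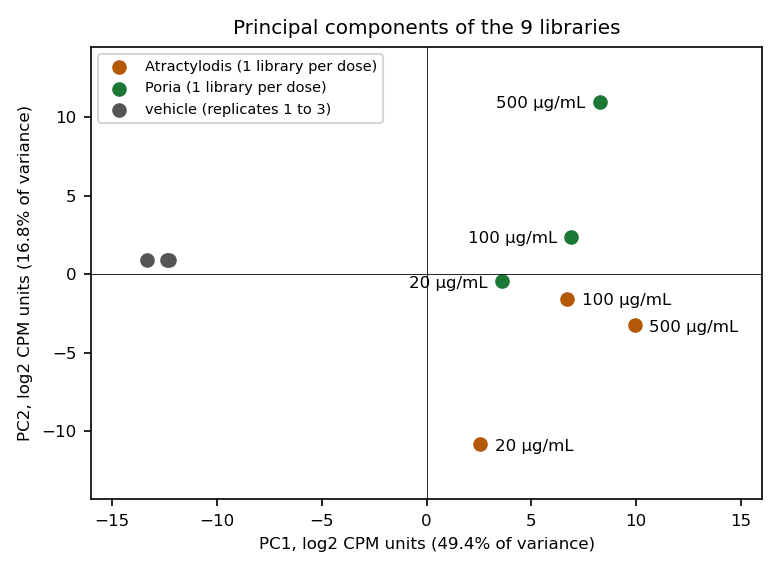
Principal components of the 9 libraries from 11583 genes. The first component (49.4% of the variance) separated the 3 vehicle libraries from the 6 treated ones. The second (16.8%) placed Poria at 500 µg/mL at 10.98 and Atractylodis at 20 µg/mL at -10.83.

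**Figure D2:**
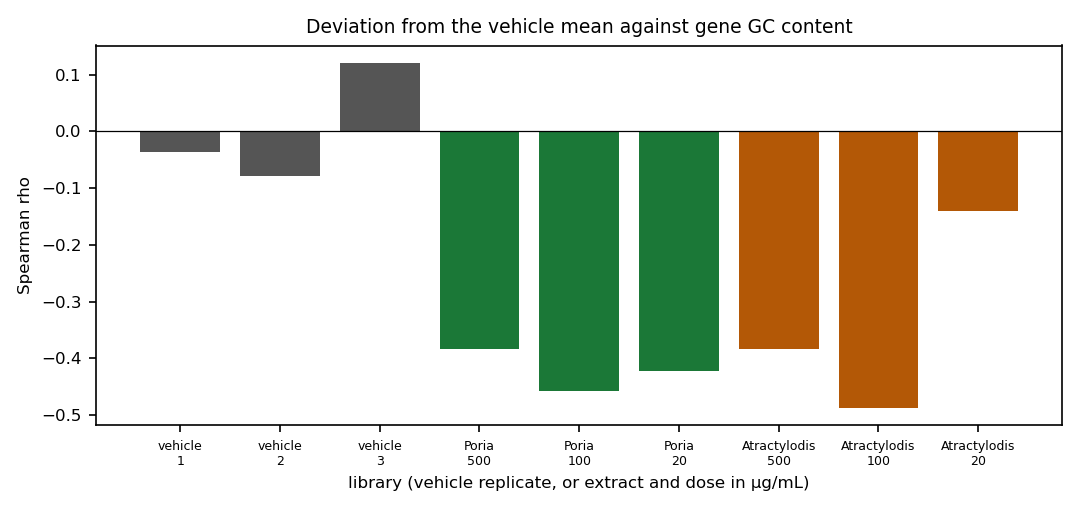
Spearman rho between each library's log2 deviation from the vehicle mean and gene GC content. Vehicle libraries lay between -0.078 and 0.121, and treated libraries between -0.487 and -0.14.

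Genes of the NRF2 antioxidant response rose with the dose of Poria extract. NQO1 (ENSG00000181019, chromosome 16, 69706996 to 69726951, minus strand), a quinone reductase, rose from 130 ± 0.701 CPM in vehicle to 150, 190 and 247 CPM at 20, 100 and 500 µg/mL (slope 0.30 ± 0.02, adjusted p = 7.7e-07). AKR1B10 (ENSG00000198074, chromosome 7, 134527592 to 134541408, plus strand), an aldo-keto reductase, rose from 3.23 ± 0.14 to 7.66 CPM (slope 0.41 ± 0.04, adjusted p = 3.9e-06). The cystine transporter gene SLC7A11, which feeds glutathione synthesis, rose from 95.3 ± 1.55 to 184 CPM (slope 0.31 ± 0.03, adjusted p = 0.00015). Within the treated libraries alone, NQO1 (slope 0.36, adjusted p = 0.00046), SLC7A11 (0.39, 0.00046) and AKR1B10 (0.40, 0.0032) also rose, and each kept its call after the GC correction (adjusted p = 2.1e-05, 0.0089 and 1e-05). Of 22 listed NRF2 genes, 12 rose and 0 fell, or 14 and 0 when adjusted over the list alone (camera adjusted p = 3.5e-16). With an estimated correlation between the genes, the list had adjusted p = 0.17. AKR1C1, AKR1C2 and AKR1C3 also rose (slopes 0.30, 0.23 and 0.34), but these paralogs share sequence, so the counts of each are uncertain. SERPINB3, a protease inhibitor with the close paralog SERPINB4, had the largest slope among them (0.44 ± 0.06, adjusted p = 9e-05) and the same uncertainty. Its slope within the treated libraries was 0.22 (adjusted p = 0.17).

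Targets of the aryl hydrocarbon receptor rose with Poria as well, 5 of 7 (6 when adjusted over the list alone), and 1 fell (camera adjusted p = 6.7e-10; adjusted p = 0.15 with an estimated correlation). ALDH1A3, which makes retinoic acid, rose from 701 ± 3.82 to 1236 CPM at 500 µg/mL (slope 0.25 ± 0.02, adjusted p = 2.8e-06). CYP1B1, a cytochrome P450 under this receptor's control, rose from 115 ± 4.41 to 194 CPM (0.23 ± 0.03, 0.00028). The classic target CYP1A1 was near the limit of detection at 0.92 CPM in vehicle and rose to 2.09 CPM (0.34 ± 0.09, 0.012), a call that ended without the Poria library at 500 µg/mL (slope 0.20, adjusted p = 0.4). The receptor's repressor gene AHRR rose by 0.12 per step (adjusted p = 0.0062) and lost its call in the same way (0.06, 0.33). The member that fell was SLC7A5, an amino acid transporter gene (-0.14). FOXO targets and PI3K-AKT feedback genes rose in 7 of 17 and fell in 1, or 10 and 2 over the list alone (camera adjusted p = 0.0034; 0.15 with an estimated correlation), with SGK1, a kinase under glucocorticoid and PI3K control, among the clearest (0.15 ± 0.02, adjusted p = 6.9e-05). CITED2 was the member that fell (-0.10). EGR1, an early growth response transcription factor, rose from 19.8 ± 1.49 to 36.4 CPM (0.27 ± 0.03, 0.00012). ALDH1A3, CYP1B1, SGK1 and EGR1 also passed within the treated libraries (adjusted p = 2.9e-06, 7.3e-05, 0.0032 and 0.0012).

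TXNIP (ENSG00000265972, chromosome 1, 145992435 to 145996600, minus strand), which restrains glucose uptake and binds thioredoxin, changed mainly at 1 dose. It stood at 10.3 ± 0.71 CPM in vehicle, and at 9.58, 16.3 and 217 CPM at 20, 100 and 500 µg/mL of Poria. The rise at the top dose was 21.0-fold (log2 4.39) in 1 library. The TXNIP relative ARRDC4 (ENSG00000140450, chromosome 15, 97960698 to 97973838, plus strand), an arrestin-domain gene under the same glucose-sensing factors, went from 6.69 ± 0.68 to 33.4 CPM (5.00-fold, log2 2.32). The trend calls of both, at adjusted p = 0.012 and 0.033, rest on that 1 library: without it the slopes were 0.26 (adjusted p = 0.24) and 0.00 (0.98). ARRDC4 also lost its trend call without any 1 of the vehicle libraries, with adjusted p between 0.063 and 0.082. Neither slope passed the test within the treated libraries (adjusted p = 0.068 and 0.096). NPTX1, a neuronal pentraxin gene, rose from 4.84 ± 0.32 to 11.5 CPM (0.35 ± 0.08, adjusted p = 0.011) and likewise had a slope of 0.05 (0.68) without that library.

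Chaperones of the endoplasmic reticulum fell with Poria, 11 of 18 and 0 up (16 fell when adjusted over the list alone; camera adjusted p = 1e-12, or adjusted p = 0.15 with an estimated correlation). CALR, which encodes calreticulin, fell from 1906 ± 5.55 to 1631, 1501 and 1327 CPM (slope -0.17 ± 0.02, adjusted p = 4.7e-05). MANF, a secreted stress factor, fell by 0.18 per step (adjusted p = 4e-05), PDIA4, a disulfide isomerase, by 0.15 (6.3e-05) and HYOU1, a large chaperone, by 0.12 (0.00017). All 4 also fell within the treated libraries (adjusted p = 0.0034, 0.0054, 0.0022 and 0.018) and after the GC correction (0.0003, 0.0002, 0.0003 and 0.0011). HERPUD1, part of the degradation complex of this compartment, had the steepest slope (-0.31 ± 0.06, adjusted p = 0.017), but not without Poria at 500 µg/mL (-0.25, 0.19) or without vehicle replicate 1 (-0.30, 0.05). The stress transcription factor gene DDIT3 (ENSG00000175197, chromosome 12, 57516588 to 57521737, minus strand) fell from 34.1 ± 1.59 to 19.0 CPM (-0.27 ± 0.04, 0.00043; within the treated libraries 0.038). Of the 21 listed integrated stress response genes 6 fell and 2 rose, or 9 and 4 over the list alone (camera adjusted p = 0.18), and SLC7A11 and STC2 were the members that rose.

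Part of the TGF-beta, YAP and matrix genes and of the metallothioneins also fell with Poria. TAGLN, an actin-binding gene of contractile cells, fell from 356 ± 8.73 to 228 CPM (-0.21 ± 0.03, adjusted p = 0.00032), and 10 of 14 TGF-beta and YAP targets fell with it while CCN1 rose (11 and 1 over the list alone; camera adjusted p = 4.7e-07, 0.25 with an estimated correlation). ANKRD1, a YAP target, fell by 0.23 per step (0.00054), although its slope within the treated libraries was -0.13 (0.32). The TGF-beta and YAP list was not called within the treated libraries with the GC correction (1 of 14 fell, camera adjusted p = 0.054). COL1A1, the main fibrillar collagen chain, fell by 0.15 (7.4e-05), with 11 of 22 matrix genes down and 0 up (11 and 1 over the list alone; camera adjusted p = 2.2e-05, 0.15 with an estimated correlation). Of 13 metalloproteinase and inhibitor genes 4 fell, among them the plasminogen activator gene PLAT (-0.16 ± 0.02, 6e-05), and ADAMTS1 rose (the same counts over the list alone; camera adjusted p = 0.018, 0.39 with an estimated correlation). That list was no longer called after the GC correction (adjusted p = 0.087) or within the treated libraries (0.51). MT1E, MT1X and MT2A, zinc-binding metallothioneins, fell by 0.43 (adjusted p = 0.0047), 0.28 (0.00047) and 0.23 (0.002), which were 3 of 6 listed members (3 also over the list alone; camera adjusted p = 1.8e-04, 0.26 with an estimated correlation). These paralogs share sequence, so the split between them is uncertain, and the MT1E call ended without Poria at 500 µg/mL (-0.33, 0.082). TAGLN, COL1A1 and PLAT also passed within the treated libraries (adjusted p = 0.013, 0.029 and 0.0065), as did MT1E and MT1X (0.0006 and 0.00079), and MT2A did not (0.4).

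The cyclin gene CCND1 and part of the cholesterol and ribosomal protein genes fell with Poria as well. CCND1 fell by 0.16 per step (adjusted p = 0.00026), but its slope within the treated libraries was -0.06 (0.3). Of 24 cholesterol genes 9 fell and 0 rose (10 and 0 over the list alone; camera adjusted p = 3e-04, 0.30 with an estimated correlation). INSIG1, a sterol sensor gene, fell by 0.12 (0.0064), with no slope within the treated libraries (0.01, adjusted p = 0.9). Ribosomal protein genes fell in 11 of 25 and rose in 0 (14 over the list alone; camera adjusted p = 2.2e-06, 0.26 with an estimated correlation). After the GC correction 7 of 25 fell (camera adjusted p = 0.00024). With that correction within the treated libraries 0 of 25 passed, and the list was not called (0.13). Long nuclear RNAs rose in 4 of 7 (6 over the list alone; camera adjusted p = 1.1e-04, 0.17 with an estimated correlation, and 0.88 within the treated libraries), for example MEG3, an imprinted tumour suppressor RNA (0.19 ± 0.03, adjusted p = 0.0041). The neurofilament gene NEFL fell by 0.21 (0.0035), a call that ended without Poria at 500 µg/mL (-0.07, 0.42). SOX9, a glial transcription factor, fell by 0.16 (6.6e-05). Its slope also passed within the treated libraries (adjusted p = 0.038), whereas that of MEG3 did not (0.052).

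The other lists were not called for the Poria trend from vehicle by camera. Within the treated libraries with the GC correction, camera called heat shock genes (adjusted p = 0.0053) and histones (0.044) higher and astrocyte markers lower (0.031). Further lists called there are given under the other observations. Heat shock genes split, with HSPH1 and HSPA8 among 5 of 13 that rose and HSPB1 (-0.17 ± 0.02, adjusted p = 0.00015, but 0.36 within the treated libraries) and DNAJB1 falling (camera adjusted p = 0.40). Fatty acid synthesis genes rose in 3 of 12 and fell in 4, 5 over the list alone (0.52). Fatty acid oxidation genes (12 tested) had a median slope of 0.01 and a mean of -0.02 with no member past the test (0.74). Liver X receptor targets had 1 of 10 down, 0 over the list alone (0.67), p53 targets 2 up and 3 down of 19, 3 and 3 over the list alone (0.86), and hypoxia genes 1 up and 4 down of 20 (0.34). DNA replication genes fell in 4 of 23, but in 1 over the list alone (0.46), and mitosis genes in 5 of 24 with CENPE up (0.18, and 0.0054 after the GC correction). The NF-kB list had 2 up and 3 down of 19, a median of -0.01 and a mean of 0.03 (0.94). The cytokine gene IL1B (0.18, adjusted p = 0.0082, but 0.08 and 0.47 without Poria at 500 µg/mL) rose and CCL2, a monocyte chemokine gene, fell (-0.28, 0.012). Interferon genes rose in 3 of 22 and fell in 1 (0.74), immediate early genes rose in 2 of 22 and fell in 4 (0.45), and autophagy genes rose in 1 of 20 and fell in 5 (0.12). Iron genes rose in 2 of 11 and fell in 1, 2 over the list alone (0.14). Oxidative phosphorylation genes rose in 2 of 21 (0.76), while no mitochondrially encoded mRNA (13 tested, 0.072) and no histone gene (8 tested, 0.77) passed. Among cell type markers, astrocyte genes had 1 up and 3 down of 7, a median of 0.04 and a mean of -0.02 (0.13, and 0.036 after the GC correction). Mesenchymal genes had 1 up and 3 down of 12, 2 and 3 over the list alone (0.54), neuronal genes 2 down of 8 with a median of -0.04 and a mean of 0.02 (0.33), myeloid genes 1 down of 6 (0.075), epithelial genes 1 down of 4 (0.28) and endothelial genes 1 up of 5 with a median of -0.05 and a mean of 0.01 (0.44).

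In all, 3815 of 18356 genes had a trend over vehicle and the Poria doses by edgeR, 1681 up and 2134 down, with 18 up and 15 down by at least 1.5-fold per step. This trend includes the step from vehicle, and 2613 of these genes were also called between treated and vehicle libraries in the same direction. The slopes within the treated libraries passed for 449 genes (220 up, 229 down), and 2808 changed after the GC correction, of which 2159 were shared with the first count. Without vehicle replicate 1 the count was 2541. With dose itself in place of the dose step it was 125 (77 up, 48 down), and the mean of the 3 doses, which ignores their order, called 4231. Chance assignment of the dose steps over the 6 libraries of this fit, vehicle included, was excluded only if the libraries are independent. With the real doses 4152 genes passed. At most 2553 passed in any other of the 60 assignments drawn, where the doses 100 and 20 were exchanged. An order that was not drawn, with 100 and 500 exchanged and vehicle kept at 0, gave 2966. Too few orders with vehicle kept at 0 exist for a share under 0.05, so a chance order of the doses was not excluded.

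**Figure D3:**
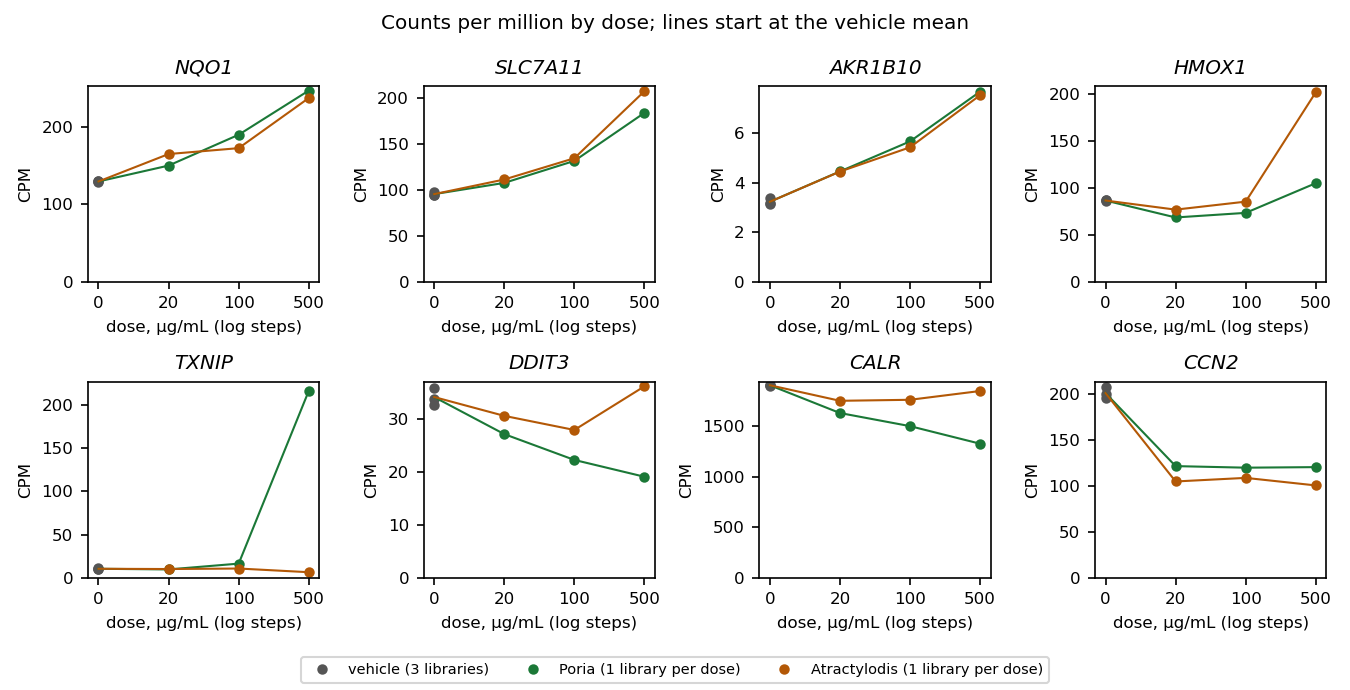
CPM of 8 genes by dose, with vehicle as 3 points and 1 library per extract and dose. NQO1 reached 247 CPM with Poria and 237 CPM with Atractylodis at 500 µg/mL, and TXNIP 217 and 6.35 CPM.

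Genes of the NRF2 list also rose with Atractylodis dose. NQO1 reached 237 CPM at 500 µg/mL (slope 0.28 ± 0.02, adjusted p = 2.9e-06), SLC7A11 207 CPM (0.35 ± 0.03, 0.00014) and AKR1B10 7.52 CPM (0.40 ± 0.04, 9.7e-06). All 3 also rose within the treated libraries (adjusted p = 0.0025, 0.00014 and 0.0035) and after the GC correction (3.5e-05, 0.0053 and 2.3e-05). Of 22 NRF2 genes 13 rose and 0 fell, or 16 over the list alone (camera adjusted p = 2.7e-19; adjusted p = 0.15 with an estimated correlation). The heme oxygenase gene HMOX1 stood at 86.8 ± 0.98 CPM in vehicle, and at 77.1, 85.6 and 202 CPM at 20, 100 and 500 µg/mL. The rise at the top dose was 2.33-fold in 1 library, with a trend at adjusted p = 0.075. Iron genes rose in 5 of 11 and fell in 1, or 8 and 1 over the list alone (camera adjusted p = 2.3e-06; 0.15 with an estimated correlation), and the ferritin heavy chain gene FTH1 (0.13, adjusted p = 0.012) had a slope of 0.02 (0.7) without the Atractylodis library at 500 µg/mL. The peroxidase gene GPX4, which limits ferroptosis, was the member that fell (-0.06). Aryl hydrocarbon receptor targets rose in 3 of 7 (camera adjusted p = 0.0013; 0.32 with an estimated correlation), namely CYP1B1, ALDH1A3 and NQO1, while CYP1A1 had a slope of 0.00, and the list was not called within the treated libraries (0.14). The slopes of CYP1B1 and ALDH1A3 within the treated libraries were 0.04 and 0.00 (adjusted p = 0.49 and 0.98). The ALDH1A3 call (0.08, 0.017) ended without vehicle replicate 3 (0.07, 0.054) or without Atractylodis at 500 µg/mL (0.09, 0.11).

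Part of the integrated stress response genes rose with Atractylodis dose. DDIT4, an inhibitor of mTOR signalling, rose from 56.0 ± 3.11 to 89.9 CPM (0.21 ± 0.02, adjusted p = 6.1e-05), also within the treated libraries (0.0013). ASNS, asparagine synthetase, rose from 59.1 ± 1.1 to 85.5 CPM (0.14 ± 0.03, 0.0022), but its slope was 0.05 (0.34) without Atractylodis at 500 µg/mL. TRIB3, a pseudokinase gene downstream of ATF4, behaved alike, at 0.11 (0.024) and 0.01 (0.94) without that library, and at 0.11 (0.059) without vehicle replicate 2. In the integrated stress response list 8 of 21 rose and 0 fell, also over the list alone (camera adjusted p = 3.5e-05; 0.32 with an estimated correlation). GDF15 (ENSG00000130513, chromosome 19, 18374731 to 18389176, plus strand), a stress cytokine gene, rose from 4.32 ± 0.55 to 9.54 CPM (0.32 ± 0.07, adjusted p = 0.011), a call that rested on the top dose (0.04, 0.77 without it). SQSTM1, an autophagy receptor gene, went from 554 ± 2.44 to 824 CPM (0.15 ± 0.03, 0.0018; without the top dose 0.07, 0.23), and autophagy genes rose in 7 of 20 and fell in 1, or 8 and 1 over the list alone (camera adjusted p = 0.0067; 0.47 with an estimated correlation). CREBRF, a regulator of stress signalling, rose by 0.28 per step (adjusted p = 0.00022, but 0.053 within the treated libraries). ABCA1, the cholesterol exporter gene, rose by 0.12 (0.0017; without the top dose 0.07, 0.22) and was the only 1 of 10 liver X receptor targets past the test (camera adjusted p = 0.29).

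Part of the cell division genes and 2 keratin genes fell with Atractylodis. KRT18, a keratin gene of simple epithelia, fell from 223 ± 3.63 to 211, 162 and 114 CPM (-0.29 ± 0.03, adjusted p = 0.00023), also within the treated libraries (slope -0.44, adjusted p = 1.5e-09). It fell together with its partner KRT8 (-0.15, adjusted p = 0.0027, but -0.09 and 0.21 without the top dose), which made 2 of 4 epithelial genes (camera adjusted p = 0.0021; 0.15 with an estimated correlation). CDC20, an activator of anaphase, fell by 0.14 per step (adjusted p = 0.00014) and AURKB, a mitotic kinase gene, by 0.17 (0.00035). Both also fell within the treated libraries (0.0013 and 0.0088), and of 24 mitosis genes 15 fell and 0 rose, or 16 over the list alone (camera adjusted p = 6.7e-13; 0.17 with an estimated correlation). Of 23 DNA replication genes 9 fell, also over the list alone (camera adjusted p = 1.3e-04; 0.39 with an estimated correlation), among them TK1, thymidine kinase (-0.14, adjusted p = 0.00044). CCND1 fell by 0.18 (0.00023). TUFT1, an adhesion-linked gene, and S1PR1, a lipid receptor gene, fell by 0.32 (0.00034) and 0.33 (0.00035). Within the treated libraries TK1, CCND1 and TUFT1 also passed (adjusted p = 0.00073, 0.0091 and 0.0079), and S1PR1 did not (0.088).

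Part of the TGF-beta, YAP and NF-kB genes fell too. THBS1, which encodes a matrix glycoprotein that activates TGF-beta, fell from 2334 ± 18.2 to 1436 CPM (-0.22 ± 0.03, adjusted p = 0.00039), TAGLN by 0.20 (0.00064) and ANKRD1 by 0.31 per step (0.00021). The slopes within the treated libraries passed for THBS1 (adjusted p = 0.0036) and not for TAGLN (0.054) or ANKRD1 (0.086). Of 14 TGF-beta and YAP targets 10 fell and 0 rose, or 11 over the list alone (camera adjusted p = 1.6e-12; 0.15 with an estimated correlation). CCL2 fell from 37.9 ± 1.1 to 17.0 CPM (-0.37 ± 0.06, 0.0053), although not past the test without the top dose (-0.42, 0.063). Among 19 NF-kB genes 6 fell and 1, SOD2, rose (the same over the list alone; camera adjusted p = 7.7e-04, 0.47 with an estimated correlation). Immediate early genes fell in 7 of 22, 8 over the list alone, with EGR1 rising (0.16, adjusted p = 0.0052; camera adjusted p = 0.011, 0.57 with an estimated correlation). Matrix genes fell in 7 of 22, 9 over the list alone (camera adjusted p = 0.0021; 0.24 with an estimated correlation). Metalloproteinase and inhibitor genes fell in 4 of 13, or 5 with 1 up over the list alone (0.003; 0.31 with an estimated correlation), led by PLAT (-0.20 ± 0.02, adjusted p = 1.5e-05). The sterol sensor gene INSIG1 (-0.20, 0.00056) and SQLE, a rate-limiting enzyme gene of cholesterol synthesis (-0.12, 0.0012), were among 8 of 24 cholesterol genes that fell, 10 over the list alone (camera adjusted p = 6.1e-06; 0.19 with an estimated correlation). The SQLE call ended without the top dose (-0.07, 0.14). The NF-kB (adjusted p = 0.87), immediate early (0.85) and metalloproteinase (0.58) lists were not called within the treated libraries.

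Ribosomal protein genes fell in 6 of 25 with Atractylodis (camera adjusted p = 5.3e-04; 0.39 with an estimated correlation), and long nuclear RNAs rose in 4 of 7, or 7 over the list alone (3e-06; 0.15 with an estimated correlation). The long nuclear RNA list was not called within the treated libraries with the GC correction (camera adjusted p = 0.15). FOXO targets rose in 6 of 17 and fell in 1, CITED2, or 8 and 1 over the list alone (0.0075; 0.15 with an estimated correlation). Oxidative phosphorylation genes rose in 4 of 21, for example ATP5F1A, an ATP synthase subunit gene (0.07, adjusted p = 0.031; camera 0.048, 0.61 with an estimated correlation). The ATP5F1A call ended when any 1 vehicle library was left out, at adjusted p = 0.098, 0.06 and 0.096. Mitochondrially encoded mRNAs were called lower as a list (0.019; 0.62 with an estimated correlation) with 0 of 13 members past the test, and the list was not called after the GC correction (0.062). Neither it (0.27) nor the oxidative phosphorylation list (0.74) was called within the treated libraries. Hypoxia genes rose in 4 of 20 and fell in 2, or 5 and 2 over the list alone (0.098, and 0.027 after the GC correction). Within the treated libraries with the GC correction, camera called hypoxia genes higher (adjusted p = 7.3e-06) and fatty acid synthesis genes lower (0.0017). Lists not called were fatty acid synthesis (2 up and 3 down of 12, 4 down over the list alone; 0.41), fatty acid oxidation (0 of 12; 0.28), metallothioneins (1 up and 1 down of 6, 2 down over the list alone; 0.48), chaperones of the endoplasmic reticulum (1 up of 18; 0.94, but called higher within the treated libraries, 3 of 18, 4 over the list alone, at 0.00047, or 0.38 with an estimated correlation) and heat shock (1 up and 1 down of 13; 0.74). The same held for p53 targets (2 up and 2 down of 19, 4 up over the list alone; 0.74), interferon genes (2 up and 2 down of 22; 0.48) and histones (1 down of 8; 0.39). Astrocyte markers had 1 up and 2 down of 7, a median of 0.00 and a mean of 0.03 (0.68). Mesenchymal markers had 2 up and 3 down of 12, 3 and 3 over the list alone (0.41), neuronal markers 0 of 8 (0.44), myeloid markers 1 down of 6 (0.31) and endothelial markers 1 up of 5, 1 up and 1 down over the list alone, with a median of 0.02 and a mean of -0.06 (0.93).

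In all, 3495 genes had a trend over vehicle and the Atractylodis doses, 1559 up and 1936 down, with 13 up and 14 down by at least 1.5-fold per step. Of these, 2737 were also called between treated and vehicle libraries in the same direction. Within the treated libraries 742 changed (276 up, 466 down), and 2658 after the GC correction, of which 2096 were shared. The count fell to 1030 without the Atractylodis library at 500 µg/mL, to 2105 without the 1 at 100 µg/mL, and to 2102, 2264 and 2157 without vehicle replicates 1, 2 and 3. Dose itself gave 67 (41 up, 26 down), and the mean of the 3 doses 4038. Chance assignment of the dose steps over the vehicle and treated libraries was excluded only if the libraries are independent. In the fit of 6 libraries 4432 genes passed with the real doses. At most 835 passed in any other of the 60 assignments drawn. With vehicle kept at 0 and only the order of the 3 doses changed, up to 2842 genes passed. Too few such orders exist for a share under 0.05, so a chance order of the doses was not excluded.

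By camera p, the extracts differed most in the chaperones of the endoplasmic reticulum (median difference -0.09), while by size the metallothioneins differed more (-0.20). The metallothioneins had a median difference of 0.03 within the treated libraries and were not called there (camera adjusted p = 0.75). The slope of CALR was lower with Poria by 0.14 ± 0.02 per step (difference -0.14, adjusted p = 0.0038), that of MANF by 0.15 (difference -0.15, 0.0038), and those of PDIA4 and HYOU1 differed by -0.13 (0.0048) and -0.09 (0.021). Of the 18 listed chaperones 9 had a lower slope with Poria and 0 a higher 1, or 15 over the list alone (camera adjusted p = 2.7e-27; adjusted p = 0.15 with an estimated correlation). At 20, 100 and 500 µg/mL, 11, 16 and 17 of the 18 were lower with Poria, by a median of -0.01, -0.13 and -0.35. Within the treated libraries alone, 7 of them had a lower slope with Poria (camera adjusted p = 1.2e-24; adjusted p = 0.11 with an estimated correlation). In the integrated stress response list 7 of 21 were lower with Poria, 12 over the list alone (3.9e-17; 0.15 with an estimated correlation), among them DDIT3 (difference -0.26, adjusted p = 0.011), ASNS (-0.17, 0.015), CHAC1, a glutathione-degrading enzyme gene (-0.26, 0.015), and NUPR1, a stress-induced chromatin factor (-0.27, 0.027). None of the gene differences in this paragraph passed without Poria or without Atractylodis at 500 µg/mL: the difference of DDIT3 then was -0.28 (0.37) and -0.15 (0.38), and that of CHAC1 -0.26 (0.37) and -0.15 (0.6). NUPR1 had -0.16 (0.53) and -0.20 (0.59), and also lost its call without vehicle replicate 3 (-0.27, 0.052). Among the named genes whose difference passed, GDF15 had the largest (-0.43 ± 0.08, 0.033), which ended without vehicle replicates 2 or 3 (adjusted p = 0.071 and 0.07).

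Higher slopes with Poria were fewer among the named genes. ALDH1A3 (difference 0.18 ± 0.02, adjusted p = 0.0032) and CCN1, a matricellular gene under YAP control (0.22 ± 0.03, 0.0032), were the clearest, and CCN1 rose with Poria (0.14, 0.0012, but 0.06 and 0.2 without its top dose) while it fell with Atractylodis (-0.08, 0.041). CEMIP (ENSG00000103888, chromosome 15, 80779343 to 80951776, plus strand), a hyaluronan-degrading factor, went from 51.4 CPM in vehicle to 62.4 with Poria and 30.3 CPM with Atractylodis at 500 µg/mL (difference 0.29, 0.0048). The tissue factor gene F3, which starts coagulation, went from 151 to 171 and 91.8 CPM (0.26, 0.019). Without Poria or Atractylodis at 500 µg/mL, CEMIP had differences of 0.21 (0.11) and 0.24 (0.38), and F3 of 0.15 (0.11) and 0.28 (0.44). KRT18 (0.16, adjusted p = 0.035) and RRM2, a ribonucleotide reductase subunit gene (0.10, 0.028), were lower with Atractylodis. ALDH1A3, CCN1, KRT18 and RRM2 lost their calls in the same 2 ways. Mitosis genes had 3 of 24 higher slopes with Poria, 18 over the list alone (camera adjusted p = 3.5e-16; 0.15 with an estimated correlation), and DNA replication 1 of 23 (2.1e-05; 0.34 with an estimated correlation). NF-kB genes had 1 of 19, 6 over the list alone (1.8e-06; 0.31 with an estimated correlation), aryl hydrocarbon receptor targets 1 of 7, 4 over the list alone (3.5e-05; 0.25 with an estimated correlation), TGF-beta and YAP targets 1 of 14, 3 over the list alone (0.028; 0.59 with an estimated correlation), and epithelial genes 1 of 4, 2 over the list alone (0.0081; 0.17 with an estimated correlation). The aryl hydrocarbon receptor targets were lower with Poria in 7 of 7 at 20 µg/mL (median -0.16), but in 1 of 7 at 100 and at 500 µg/mL (0.22 and 0.30). Against vehicle their medians at 20, 100 and 500 µg/mL were -0.06, 0.464 and 0.75 with Poria, and 0.229, -0.043 and 0.117 with Atractylodis. The order at 20 µg/mL thus went with a high value in the Atractylodis library, which lay apart on the second component. Immediate early genes were called higher with 0 of 22 past the test (0.017; 0.58 with an estimated correlation).

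Lists with lower slopes under Poria were autophagy (4 of 20, 7 over the list alone; camera adjusted p = 1.7e-11, 0.15 with an estimated correlation), metallothioneins (1 of 6, 4 over the list alone; 4.1e-06, 0.17 with an estimated correlation) and iron genes (1 of 11, 2 over the list alone; 2.3e-05, 0.15 with an estimated correlation). Hypoxia genes (2 of 20; 2.3e-05, 0.18 with an estimated correlation), liver X receptor targets (1 of 10, 2 over the list alone; 0.015, 0.26 with an estimated correlation), neuronal markers (1 of 8, 4 over the list alone; 0.0027, 0.17 with an estimated correlation) and oxidative phosphorylation (0 of 21, 2 over the list alone; 0.017, 0.57 with an estimated correlation) completed the 16 lists called. Of these, metallothioneins, liver X receptor targets (0.13) and oxidative phosphorylation (0.16) were not called within the treated libraries, and neither were the TGF-beta and YAP targets (0.26). The NRF2 list (0.59) and the cholesterol list (0.34) were not called, but within the treated libraries cholesterol genes were called higher with Poria (2 of 24, 3 over the list alone; 0.00047, 0.24 with an estimated correlation). DDIT4, SQSTM1, ABCA1 and MT1X were members with lower slopes under Poria (-0.15, -0.23, -0.12 and -0.21, adjusted p = 0.0072, 0.0038, 0.021 and 0.031). TXNIP had a difference of trends of 1.35 that did not pass (0.17).

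In all, 213 genes had different slopes, 89 higher and 124 lower with Poria. Without Poria at 500 µg/mL or without Atractylodis at 500 µg/mL the count was 0, and without vehicle replicate 3 it was 141. Only 4 swaps of the extract labels exist, too few for a share under 0.05, with 213 for the real labels and 19 for the highest other. The slopes within the treated libraries also differed in 213 genes, 61 of them in both counts. At a single dose the extracts differed in 2035 genes at 500 µg/mL (986 higher and 1049 lower with Poria), 54 at 100 µg/mL (30 and 24) and 197 at 20 µg/mL (73 and 124). Each of these compares 1 library with 1 other, with the error taken from the vehicle libraries, and DESeq2 gave 240, 13 and 56. Without vehicle replicates 1, 2 and 3 the count at 100 µg/mL was 153, 251 and 135, and at 20 µg/mL it was 424, 884 and 434. Without vehicle replicate 2 the count at 500 µg/mL was 3184.

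**Figure D4:**
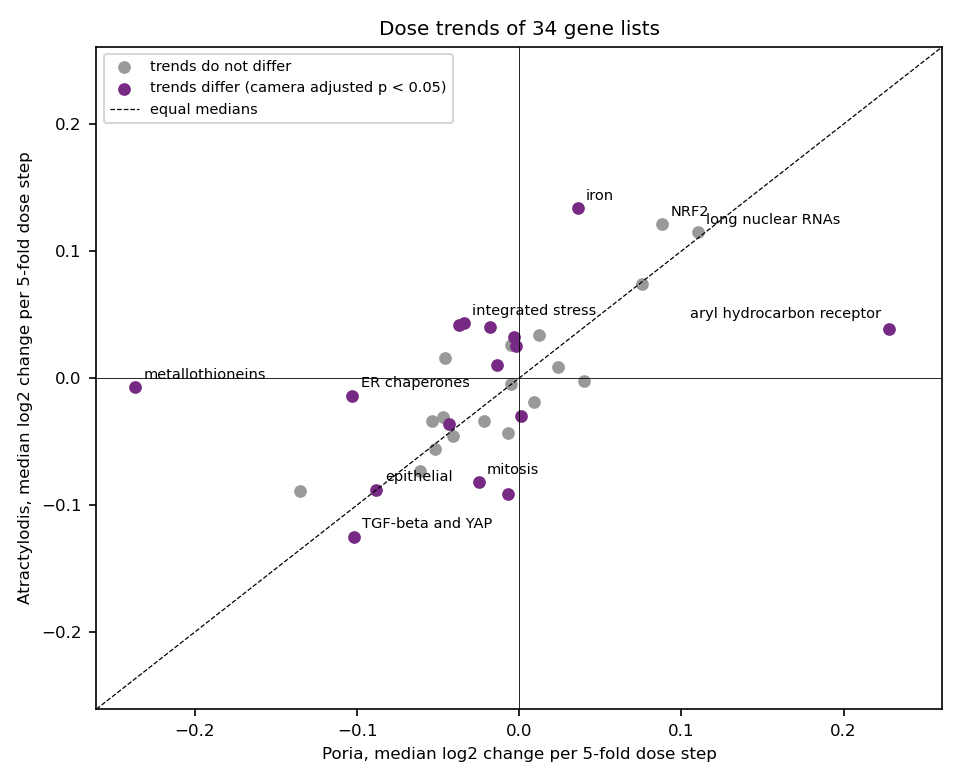
Median slope of 34 gene lists with Poria and Atractylodis, in log2 per 5-fold dose step. The chaperone list of the endoplasmic reticulum had medians of -0.10 and -0.01, and the NRF2 list of 0.09 and 0.12.

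Taken as 1 group, the treated libraries had lower TGF-beta and YAP targets and higher long nuclear RNAs than vehicle. CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373, minus strand), a matricellular YAP target, fell from 201 ± 6.33 CPM in vehicle to between 100 and 121 CPM in the 6 treated libraries (log2 -0.84 ± 0.06, adjusted p = 5.3e-07). CCL2 fell by 0.81 ± 0.10 (adjusted p = 0.00018) and TAGLN by 0.51 ± 0.05 (3.2e-06). With them, 11 of 14 TGF-beta and YAP targets fell and 0 rose, also over the list alone (camera adjusted p = 8.3e-15), and this was 1 of 2 lists called with an estimated correlation (adjusted p = 0.040). The other was the long nuclear RNAs, 5 of 7 up, 7 over the list alone (3.6e-09; adjusted p = 0.040 with an estimated correlation). That list was fixed as a sign of RNA quality, as was the list of mitochondrially encoded mRNAs, so these shifts are not read as a response of the cells. NEAT1, the scaffold of paraspeckles, rose from 296 ± 6.94 CPM to between 396 and 650 CPM (0.86 ± 0.14, 0.0035), MEG3 by 0.47 (2.7e-06) and MALAT1, a nuclear speckle RNA, by 0.37 (2.9e-05). MARK2 (ENSG00000072518, chromosome 11, 63838928 to 63911019, plus strand), a polarity kinase gene, doubled from 17.3 ± 2.22 CPM (1.00, adjusted p = 0.0013). SERPINB3 rose by 1.00 (0.00042), and AKR1B10 by 0.86 (0.012), which was no longer past the test without vehicle replicate 1 (0.84, 0.057) or 3 (0.85, 0.052).

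Other lists called for treated against vehicle were lower, except NRF2 and FOXO targets. Mitosis genes fell in 10 of 24 with 1 up, or 12 and 1 over the list alone (camera adjusted p = 5.6e-04; 0.78 with an estimated correlation). NF-kB genes fell in 6 of 19, 8 over the list alone (1.1e-04; 0.70 with an estimated correlation), and immediate early genes in 11 of 22 with 1 up, EGR1 (3e-04; 0.36 with an estimated correlation). Ribosomal protein genes fell in 8 of 25 (1.7e-04; 0.78 with an estimated correlation) and metalloproteinase genes in 6 of 13 (0.0024; 0.088 with an estimated correlation). Cholesterol genes fell in 8 of 24 (0.018), matrix genes in 10 of 22 with 1 up (0.016), chaperones of the endoplasmic reticulum in 4 of 18, 2 over the list alone (0.021) and mitochondrially encoded mRNAs in 0 of 13 (0.027), each at adjusted p = 0.78 with an estimated correlation. NRF2 genes rose in 4 of 22 (0.0031; 0.78 with an estimated correlation) and FOXO targets in 6 of 17 with 1 down (0.039; 0.73 with an estimated correlation). After the GC correction the mitochondrial mRNA list was no longer called (camera adjusted p = 0.061) and the FOXO list stood at the threshold (0.05). The oxidative phosphorylation list was then called higher (5 of 21 up and 1 down, 0.016). The actin gene ACTB, often taken as constant, fell from 10010 ± 221 CPM to 7315 with Poria and 7369 CPM with Atractylodis at 500 µg/mL (log2 -0.38 ± 0.05 over all treated libraries, 2.1e-05). GAPDH, another common reference, fell by 0.25 ± 0.04 (0.00021), and its dose trends ended after the GC correction (adjusted p = 0.15 for both extracts).

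In all, 4639 genes differed between treated and vehicle libraries, 2197 up and 2442 down, with 210 up and 98 down by at least 1.5-fold. After the GC correction the count was 3956, and 3067 genes kept their call and direction. Without vehicle replicate 1 the count was 2987. In the called direction, the 4639 genes had a median log2 shift from vehicle of 0.21, 0.244 and 0.249 at 20, 100 and 500 µg/mL of Poria. With Atractylodis the median shift was 0.181, 0.241 and 0.267, so most of it was present at the lowest dose of both extracts. The genes were chosen on the same libraries. All splits of the 9 libraries into 6 and 3 gave at most 1 gene besides the real 4639. A chance split was thus excluded only if the libraries are independent, which the labels do not state. At a single dose against vehicle, Poria changed 3647 genes at 20 µg/mL (1546 up, 2101 down), 4689 at 100 µg/mL (2065, 2624) and 5788 at 500 µg/mL (2650, 3138). Atractylodis changed 3213 (1378, 1835), 4631 (2080, 2551) and 5692 (2648, 3044). DESeq2 called far fewer, with a lower share up: 682 (131 up), 1081 (228) and 1480 (403) for Poria, and 528 (97), 1104 (276) and 1579 (432) for Atractylodis.

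Genes called for both extracts nearly all moved the same way. Of the genes called for both trends 892 rose and 1265 fell with both, where 142.8 and 225.1 were expected from independent calls, and 6 went in opposite directions. The overlap of Poria and Atractylodis calls, 2157 genes, fell to 1170, 1298 and 1250 without vehicle replicates 1, 2 and 3, to 880 without Atractylodis at 500 µg/mL and to 1358 without Atractylodis at 100 µg/mL. The slopes of the extracts had a Pearson correlation of 0.581, but both are measured against the same 3 vehicle libraries: simulated groups with no change gave 0.403. Their covariance was 0.0196, against 0.0039 in the simulations, which gave a mean of 0 shared calls. The simulations hold no difference in handling between vehicle and treated libraries. Within the treated libraries, where the slopes share no library, the correlation was 0.014. There 23 genes rose and 34 fell with both extracts against 3.3 and 5.8 expected, and 15 went opposite ways.

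Several genes of interest did not pass. The cell cycle inhibitor gene CDKN1A, a p53 target, had slopes of -0.01 (adjusted p = 0.89) and 0.06 (0.18) for Poria and Atractylodis. The cytokine gene IL6 had 0.07 (0.36) and -0.01 (0.95). CXCL8, a neutrophil chemokine gene, had a Poria trend of 0.25 (0.096) but passed within the treated libraries (0.61, adjusted p = 1.5e-06), moving from 9.17 CPM at 20 to 21.2 CPM at 500 µg/mL. The astrocyte filament gene GFAP was too low to test, with 0 to 7 counts per library, as were the astrocyte markers AQP4 (0 to 3) and ALDH1L1 (0 to 2). Only 3 of 12 hepatocyte markers could be tested, so that list was not used. VIM, the mesenchymal filament gene, stood at 5987 CPM in vehicle and fell with both extracts (-0.07, adjusted p = 0.014, and -0.11, 0.002). Its Poria call ended without vehicle replicate 1 (-0.07, 0.058) or 3 (-0.07, 0.052), and its Atractylodis call without the top dose (-0.10, 0.077).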

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

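All results given here are differences between the extracts, and for these the test of label swaps and the test of the doses were written before their results were seen. The dose trends of the extracts differed by the edgeR test of the difference itself in 213 genes and by camera in 16 gene lists, and at single doses the extracts differed in 2035 genes at 500 µg/mL, 54 at 100 µg/mL and 197 at 20 µg/mL. With an estimated correlation no list was called (adjusted p of at least 0.15), and without Poria or without Atractylodis at 500 µg/mL no gene differed by trend. Each single dose compares 1 library with 1 other, with the error taken from the vehicle libraries, and DESeq2 gave 240, 13 and 56 genes. Lower slopes with Poria than with Atractylodis, in log2 per dose step, were found among the named genes for GDF15 (-0.43), NUPR1 (-0.27), PCSK1 (-0.27), DDIT3 (-0.26), CHAC1 (-0.26), SQSTM1 (-0.23), MT1X (-0.21), ASNS (-0.17), DDIT4 (-0.15), MANF (-0.15), CALR (-0.14), PDIA4 (-0.13), PHLDA3 (-0.12), CTSD (-0.12), ABCA1 (-0.12), SLC2A3 (-0.12), SYT1 (-0.11), BNIP3 (-0.11), FAP (-0.10), PDIA6 (-0.10), HYOU1 (-0.087), NEU1 (-0.084) and EDEM1 (-0.081). Higher slopes with Poria were found for CEMIP (0.29), F3 (0.26), ANXA8L1 (0.24), LINC01119 (0.23), SLC27A2 (0.23), BIRC3 (0.23), CCN1 (0.22), ALDH1A3 (0.18), KRT18 (0.16), RRM2 (0.10) and KIF20A (0.10). The ANXA8L1 value is uncertain, since this gene has near-identical paralogs.

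The pattern weighed here is the lower expression of endoplasmic reticulum chaperones with Poria than with Atractylodis. The list was called lower with Poria (10 of 18; camera adjusted p = 9.3e-22, 0.11 with an estimated correlation) and higher with Atractylodis (3 of 18; 0.00047, 0.38 with an estimated correlation) within the treated libraries. Against vehicle, the median log2 change of the list at 20, 100 and 500 µg/mL was -0.087, -0.143 and -0.344 with Poria. With Atractylodis it was -0.076, -0.052 and 0.01, so the rise with that extract ended near the vehicle level. If only the libraries at 500 µg/mL differed, for example through a fault in 1 of them, the written prediction was at most 11 chaperones lower with Poria at 100 µg/mL. At that dose 16 of 18 chaperones were lower, against 11 of 18 at 20 µg/mL. These genes move together and each dose is 1 pair of libraries, so the explanation was left open, although the written test would have excluded it, and this was decided after the value was seen. Only 4 swaps of the extract labels exist, too few for a share under 0.05, with 1 of them the real one (213 genes, and 19 for the highest other). Each dose of each extract is 1 library, so a difference in handling between the 2 extracts was not tested. No biological explanation was tested.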

How the results depend on the processing

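The corrections for GC content and length, and the fit of treated doses only for gene lists, were chosen after seeing the data. No paired analysis was possible because the treated groups hold 1 library each, all numbered 2, so the groups share fewer than 2 replicate numbers. For each value below the cause was not tested unless given. Counts of genes past the threshold stayed within 1.5-fold under RLE scaling and under the filter of CPM of at least 1. With DESeq2, the trend difference gave 328, Poria at 500, 100 and 20 µg/mL 1480, 1081 and 682 (403, 228 and 131 higher), Atractylodis 1579, 1104 and 528 (432, 276 and 97 higher), and the extracts against each other 240, 13 and 56. With limma-voom the trend difference gave 117, and the extracts against each other 14 at 100 and 81 at 20 µg/mL. With no filter these 3 were 555, 110 and 333, and without robust estimation the last 2 were 31 and 113. With vehicle replicate 2 as the only control, which leaves fewer libraries and no test of single doses, Poria gave 1225, Atractylodis 590, the difference 132, treated against vehicle 606 and the overlap of Poria and Atractylodis calls 306. Dose itself gave 125 (77 higher) for Poria, 67 (41 higher) for Atractylodis, 54 for the difference and 11 shared. The treated doses only, which drop the step from vehicle by construction, gave 449, 742 and 57 shared, and with the GC correction 622, 486 and 47 shared. The mean of the 3 doses gave 4 genes for the difference. The GC correction gave 1305 shared calls, and at 20 µg/mL 154 genes between the extracts with 84 higher and 70 lower with Poria, against 73 and 124. With an estimated correlation 0 gene list trends were called, against 46.

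Leaving out 1 library at a time gave 2541 to 4239 genes for Poria, 1030 to 4296 for Atractylodis, 0 to 300 for their difference, 2987 to 5346 for treated against vehicle and 880 to 2464 for the overlap of Poria and Atractylodis calls. Poria at 500, 100 and 20 µg/mL gave 5465 to 6359, 4311 to 5426 and 3298 to 4448, Atractylodis 5329 to 6307, 4276 to 5277 and 2930 to 4091, and the extracts against each other 2181 to 3184, 135 to 251 and 424 to 884. Gene list calls ran from 45 to 48. Among 7489 values of 354 gene results under the alternatives, 1077 lost their call, 103 gained one and 33 changed direction with a call in either fit. Another 5, single doses with vehicle replicate 2 as the only control and so without a test, moved by at least the vehicle SD. The remaining 6271 were counted as the same. They include the other untested single doses of that kind, and any change of direction with no call in either fit. Dose itself ended 204 calls, the treated doses only 145, the GC correction 47, and leaving out Atractylodis or Poria at 500 µg/mL 75 and 45.

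Called slopes that changed direction with the treated doses only, all small, were AEN 0.035, ATP5F1A -0.021, IFI44 -0.028, IFI44L -0.019, INSIG1 0.012, JUNB 0.001, MALAT1 -0.003, PLK1 0.026, PRRX1 -0.003, SLC1A3 -0.007 and TFRC -0.013 for Poria, and ALDH1A3 -0.003 for Atractylodis. With the GC correction added, Poria slopes were AEN 0.035, ATP5F1A -0.027, CCL2 0.002, IFI44 -0.019, IFI44L -0.029, INSIG1 0.014, JUNB 0.019, MALAT1 -0.016, PLK1 0.031, PRRX1 -0.005, SLC1A3 -0.007, TFRC -0.017 and TIMP1 0.001. Those of Atractylodis were CD68 0.033, COX7A2 -0.005, GAPDH 0.042, IRF1 0.007, MMP2 0.022, PLK3 0.021, RPL8 0.001 and SLC30A1 -0.031.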

Other observations

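The tests of a shared replicate round, of RNA quality, of RNA from other cell types and of the calls that end after the GC correction were chosen only after their results were seen. Within the treated libraries alone, some gene lists were called whose trends from vehicle were not. For Atractylodis these slopes start at the library at 20 µg/mL, which lay at -10.83 on the second component. Its rho with GC content (-0.14) also differed from those of the other treated libraries. With Atractylodis, 4 of 12 fatty acid oxidation and PPAR target genes rose and 0 fell, or 6 over the list alone (camera adjusted p = 4.6e-09; adjusted p = 0.11 with an estimated correlation), and the list kept its call after the GC correction (3.6e-11). PLIN2, a lipid droplet coat gene, went from 51.7 CPM at 20 to 94.6 CPM at 500 µg/mL (slope 0.44, adjusted p = 0.0093), and CPT1A, the gate of mitochondrial fatty acid import, from 34.6 to 45.1 CPM (0.19, 0.0035). With Poria, 4 of 19 NF-kB genes rose, or 6 over the list alone (1.7e-10; 0.11 with an estimated correlation), CXCL8 among them. Immediate early genes rose in 3 of 22 with Poria, 4 over the list alone (8.3e-06; 0.13 with an estimated correlation), while EGR1 had a slope of 0.26 (0.0012). Neuronal markers fell in 4 of 8 (0.0011; 0.15 with an estimated correlation), with NEFL at -0.40 (0.0046), and myeloid markers in 1 of 6, 3 over the list alone (0.0016; 0.13 with an estimated correlation). Mitochondrially encoded mRNAs, a sign of RNA quality, were called lower there too, with 0 of 13 past the test (0.0036; 0.56 with an estimated correlation). Metallothioneins fell in 2 of 6 with Atractylodis, 4 over the list alone (1.8e-05; 0.11 with an estimated correlation).

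The first pattern weighed is that treated libraries stand apart from vehicle at every dose. For a shared round of work with replicate number 2, vehicle replicate 2 lay only 3.1% of the way from the other vehicle libraries to the treated mean on the first principal component. The labels do not say that vehicle replicate 2 was made in the same round as the treated libraries, so such a round was not excluded. Library size was excluded, since 4570 genes were called after all libraries were thinned to the smallest total. GC content or length bias was excluded as the whole cause, with 3956 calls after correction, but 1572 of the calls ended: their median log2 change went from 0.175 (median SE 0.049) to 0.092 (0.044), so 52.4% of it was left, and whether those calls were bias could not be told. RNA quality or recovery of nuclear RNA was left open as well, because long nuclear RNAs had a median change of 0.29, with 5 of 7 called higher, and mitochondrially encoded mRNAs of -0.14, but the latter list was not called with an estimated correlation (0.78) and histones were not called (0.57). A difference in handling or library batch between vehicle wells and treated wells could not be told from a response to either extract. The reason is that 0 treated libraries have another replicate number. Since the labels give no DMSO percentage for the treated libraries, a difference in solvent was not tested. A chance split was excluded only if the libraries are independent, which the labels do not state (1 of 84 splits gave as many genes, the real one).

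The second pattern is the rise of TXNIP and ARRDC4 with Poria at 500 µg/mL. If sugar carried by the extract acted through MondoA or ChREBP, the other listed targets would rise from 100 to 500 µg/mL as well, and their median change was 0.074 (bootstrap SE 0.128, 12 targets), so it could not be told. Of these, 8 were higher, with GPD1 at 1.20 and MLXIPL, the ChREBP gene, at 0.58. RNA of another cell type was left open: among neuronal, myeloid, epithelial and endothelial markers the highest median by type was 0.077 (endothelial, 5 of 5 higher), but the markers of the other types go both ways and further types were not tested. The rise was seen in 1 library.

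The last hypothesis was that both extracts change the same genes with dose. The correlation of the slopes within the treated libraries was 0.014, below the 0.1 written beforehand as excluding it. The hypothesis was nevertheless left open after this value was seen, because low-count genes dilute it: the correlation was 0.158 among genes with a mean log2 CPM of at least 2, and 57 genes were called in the same direction. For the trends from vehicle, a chance assignment of the dose steps over the vehicle and treated libraries was excluded only if the libraries are independent, which the labels do not state. Among the assignments drawn, only the real one reached its count for Poria (1 of 60) and for Atractylodis (1 of 60). That test includes the split of vehicle from treated libraries, so it does not test the order of the doses alone. With vehicle kept at 0, too few dose orders exist for a share under 0.05, so a chance order was not excluded.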
